A study of Mus musculus with 28 samples.

How the data were processed

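Skin RNA from 24 mice was measured on 28 Agilent 2-colour arrays. Per the labels' protocols, spleen cells were transferred into BALB/c-background mice to produce chronic graft-versus-host disease, and skin was taken 2 weeks later. Donor cells came from B10.D2 mice (allogeneic, called allo here) or from BALB/c mice (syngeneic, called syn). All recipients lacked Rag2, which is needed for T and B cells to form. Some lacked only Rag2, others also lacked Il13, and others also lacked Il4ra, a chain of the receptors for IL-4 and IL-13. RNA was extracted with Trizol and cleaned on columns, and it was amplified with a low-input kit, per the labels. Skin RNA carried Cy3, and a commercial reference RNA pooled from mouse cell lines carried Cy5 on every array.

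The deposited values are log2 ratios of the 2 channels, normalized within each array by the authors. Scanner software, background correction, normalization method and filters are not given in the sources used here. The log base was taken from the spacing of values that recur among dim probes. A ratio and its inverse lie apart by 2 times its logarithm. For the ratios 2, 1.5 and 1.33 of small whole numbers, the log2 spacings of 2, 1.17 and 0.83 were found in 53, 38 and 30 of 5320 pairs. The median over all spacings was 4 pairs and the highest 55. Natural logarithms would give spacings found in 3, 10 and 9 pairs, and logarithms to base 10 in 15, 11 and 13. The deposited ratios ran as reference over skin, so their sign was turned, and all values below are log2 of skin over reference. That direction rests on the dyes in the labels and on gene lists fixed for this purpose. After turning, 16 of 16 epidermal genes had a median ratio above 0 (median 5.25, array medians 4.42 to 6.24). Of 17 genes of dividing and embryonic cells, 0 lay above 0 (median -2.22, array medians -3.09 to -1.22). No pair of arrays correlated below 0: over all pairs, r across probes ran from 0.595 to 0.928, with a median of 0.845. The median of the nonzero deposited values of an array lay between -0.144 and 0.039.

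An exact 0 was treated as a ratio that was not measured. This is a reading of the values; the labels do not state it, and the alternative of keeping 0 as a value was run. The share of exact 0 ranged from 2.42% to 36.8% of probes per array, with a median of 24.4%. Between 40.9% and 54.4% of the nonzero values of an array were shared by at least 30 probes, as dim spots with whole-number intensities would give. Spot intensities were not analysed here, so no bound was set for dim probes, and the number of arrays limits the precision.

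Of 41174 probes, 32664 had 1 gene name, 45 had several and 8465 had none in the array annotation used. Names were compared with a gene table of assembly GRCm38.p6, which changed 0 symbols. No coordinates are given, because the values name no genome build. A gene's value was the mean of its most complete probes that shared a pattern of missing mice. Genes measured in at least 2 mice of each group were tested, which left 14822 of 19532 named genes, 11852 of them measured in all 24 mice. For genes called in the Rag2-/- donor comparison with several probes, 90 of 1284 had probes of opposite sign. The same held for 11 of 731 in Il13-deficient and 3 of 383 in Il4ra-deficient recipients.

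Arrays of the same mouse were averaged, so each mouse counted once. Mouse 5702 had 3 arrays, and mice 5703 and 6232 had 2 each. Arrays of the same mouse correlated at 0.904 to 0.924 over 5 pairs, against 0.772 to 0.92 for mice of the same group. Mouse 5718 carries a label that names IL14Ra; it was taken as Il4ra-deficient because the series design names only that receptor. The first 2 digits of the mouse numbers form series that may mark separate experiments, although the labels do not say so. Rag2-/- mice fell into series 57 and 61, Il4ra-deficient mice into 45 and 57, and all Il13-deficient mice into 62. Il13 genotype and number series therefore cannot be told apart where recipients are compared.

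Group means were fitted with limma 3.58.1 in R 4.3.3 over all 6 groups, with lmFit and eBayes (prior degrees of freedom 2.97, prior variance 0.0779). Tests were two-sided, and p was adjusted by the Benjamini-Hochberg method over the 14822 genes of each comparison, with 0.05 as threshold. All adjusted p below come from this fit unless another tool is named. The comparisons were allo against syn in each recipient, the difference of these donor effects between recipients, and each deficient recipient against Rag2-/- under the same donor. Of 37 gene lists, 2 served to settle direction, 33 with at least 5 measured members were tested, and those for eosinophils (2 members) and red blood cells (3 members) were not. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 33 lists. Camera with an estimated correlation and fry, which needs genes measured in all mice, were run beside it. Some genes sit on more than 1 list, such as Ccl5 on the CC chemokine and cytotoxic lists.

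Groups, comparisons, gene lists and the first set of alternative analyses were fixed before the data were examined. So was the rule for named genes. It named a fixed set (Il13, Il4, Il4ra, Rag2, Ccl2, Ccl12, Ccr2, Tgfb1 and Col1a1) and, in each donor comparison, the 8 largest rises and falls whose groups did not overlap. It also named the 3 members of each list with the smallest p in Rag2-/- recipients, and the 5 largest differences in each direction among called genes of the other comparisons. Symbols ending in Rik, predicted genes and receptor segments were counted but not named. Other members of a list named below were chosen after their values were seen.

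The alternatives fixed beforehand were median centring, quantile normalization, complete genes only, no filter, and each probe on its own. Others were all arrays with the mouse as a random block, 1 array per mouse, only the groups compared, the number series as a block, robust eBayes, array weights, and leaving out each mouse. Added after seeing the data were exact 0 kept as a value, dim repeated values treated as not measured, the share of exact 0 as a covariate, and leaving out mice 6229 and 6234.

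The fit was tested on simulated values of 14822 genes with 100 genes changed by log2 1 and 100 by log2 2. In the donor comparison of Rag2-/- recipients 66% and 93% of these were called, with 16 unchanged genes called as well. In Il13-deficient recipients the shares were 68% and 91%, and in Il4ra-deficient recipients 58% and 91%. For the differences of donor effects the shares were 28% and 80% (Il13-deficient against Rag2-/-), 30% and 77% (Il4ra-deficient against Rag2-/-), and 27% and 75% between the deficient recipients. For Il4ra-deficient against Rag2-/- mice given B10.D2 cells, 64% and 91% were called. Gene lists shifted by log2 0.5 in the Rag2-/- donor comparison were called for 29 of 33 lists, with 2 unshifted lists called. The simulated genes varied independently of each other, so these runs cannot show how camera fares where genes of a list are correlated.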

Results

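Skin of mice given allogeneic B10.D2 or syngeneic BALB/c spleen cells was compared in 3 kinds of recipient. The title of the study names IL-13 and CCL2, an attractant of monocytes, as its subjects. Rag2-/- recipients comprised 5 allo and 4 syn mice, Il13-deficient recipients 4 allo and 4 syn mice, and Il4ra-deficient recipients 4 allo and 3 syn mice. Values are log2 of the ratio of skin to reference RNA, given as mean ± SD, and a difference of 1 is a 2-fold change.

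The targeted genes gave little information on genotype. Il13 lay within 0.5 of 0, the ratio at which skin and reference gave equal signal, in all groups but allo Il13-deficient mice. Spot intensities were not analysed, so a ratio near 0 does not show that either channel held signal of a gene. Il13 levels were 0.19 ± 0.14 (SD, n = 4) in syn and 0.32 ± 0.56 (SD, n = 5) in allo Rag2-/- mice. In Il13-deficient recipients they were 0.04 ± 0.35 (SD, n = 4) in syn and -0.91 ± 0.58 (SD, n = 3) in allo mice. In Il4ra-deficient recipients they were 0.46 ± 0.51 (SD, n = 2) in syn and 0.37 ± 0.67 (SD, n = 4) in allo mice. Rag2 lay between -0.03 and 0.10 in all group means. Il4ra was 0.77 ± 0.51 (SD, n = 4) in syn and 2.08 ± 0.67 (SD, n = 5) in allo Rag2-/- mice, and -0.16 ± 0.20 (SD, n = 3) and 0.61 ± 0.21 (SD, n = 4) in Il4ra-deficient mice. In Il13-deficient mice Il4ra was -0.09 ± 0.55 (SD, n = 4) in syn and 1.54 ± 0.98 (SD, n = 4) in allo mice. Single Il4ra-deficient mice had Il4ra at -0.32, -0.22 and 0.07 (syn) and at 0.39, 0.50, 0.72 and 0.85 (allo), with 0.39 in mouse 5718. The position of these probes relative to the deleted parts is unknown, and donor cells carry intact genes, so the values neither bear out nor contradict the labels. Ccr2, the receptor of CCL2, was measured in too few mice to be tested; 1 probe lay at 3.34 in 4 of 4 syn and 6.93 in 3 of 5 allo Rag2-/- mice, and another at 0.44 in 2 of 4 and 2.64 in 4 of 5. In Il13-deficient mice the former lay at -0.08 in 1 of 4 syn and 6.66 in 2 of 4 allo mice, and in Il4ra-deficient mice at 5.46 in 1 of 3 syn and 6.27 in 3 of 4 allo mice.

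**Figure D1:**
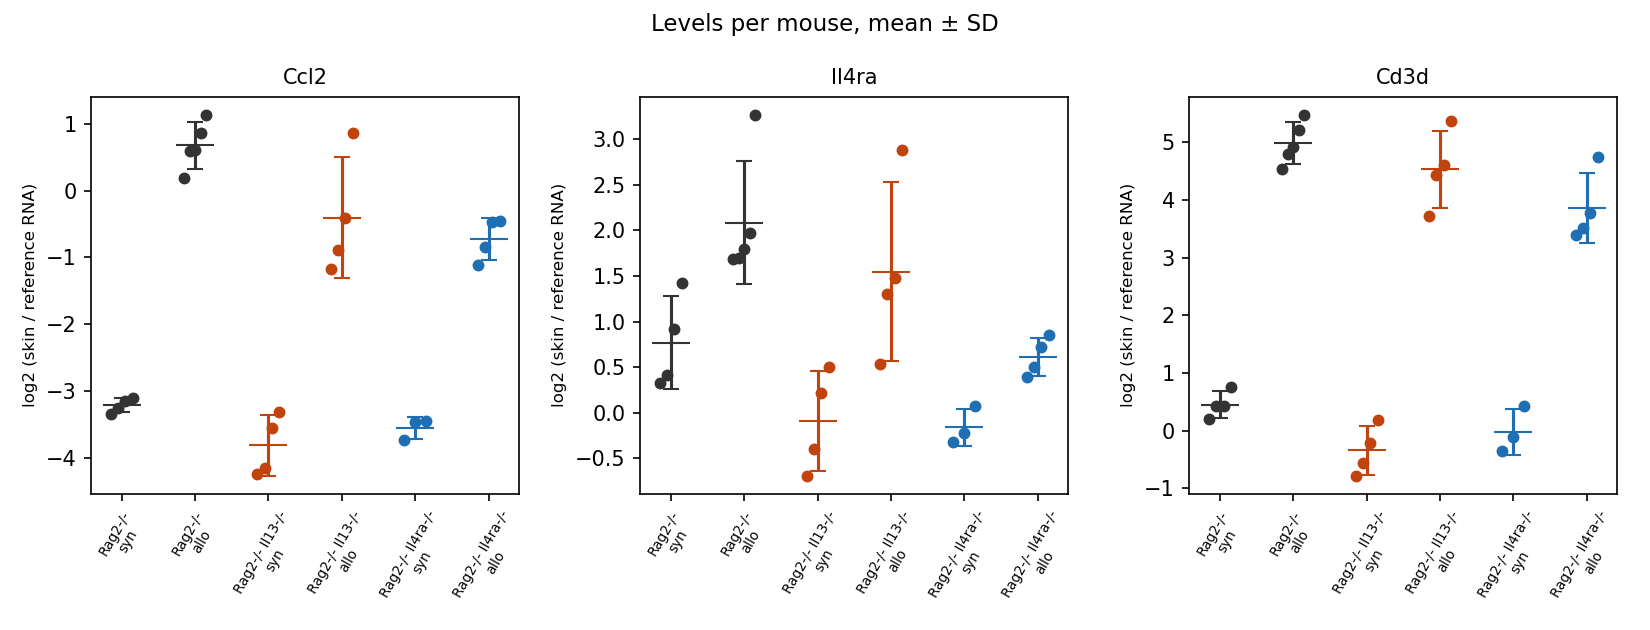
Levels of Ccl2, Il4ra and the T cell gene Cd3d in the skin of each mouse, as log2 of skin over reference RNA, by recipient and donor. Points are mice, and bars show mean ± SD of 3 to 5 mice; Ccl2 was higher in each allo mouse than in each syn mouse of the same recipient.

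The largest component of variation separated donors. The first principal component of the 11852 genes measured in all mice held 46.6% of the variance, and all 13 allo mice (3.6 to 62.7) lay above all 11 syn mice (-40.8 to -27.4). The second held 16.0%, and on it 2 syn Il13-deficient mice, 6229 at 48.5 and 6234 at 75.1, stood apart from all others (-20.5 to 12.2). Hair follicle and proliferation genes ranked high on this component, and interferon-gamma, type I interferon, macrophage, muscle, complement and MHC class II genes low.

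**Figure D2:**
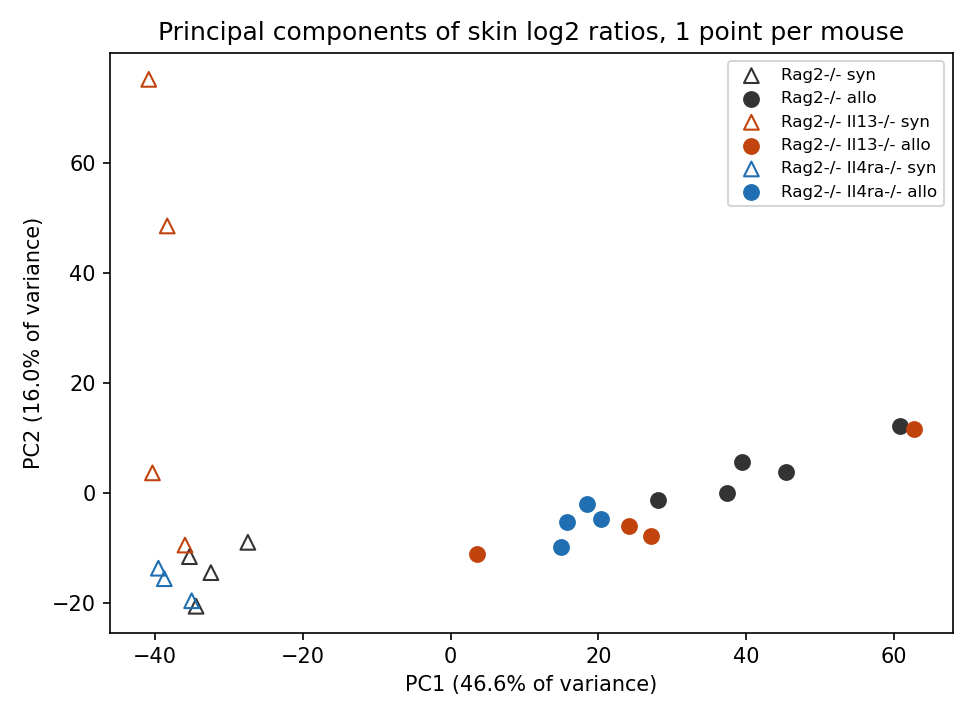
Scores of 24 mice on the first and second principal components (46.6% and 16.0% of the variance). Filled circles are allo and open triangles syn mice; syn Il13-deficient mice 6229 and 6234 lie at 48.5 and 75.1 on the second component.

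Allogeneic cells changed the skin of Rag2-/- recipients widely, with interferon, T cell, cytotoxic and monocyte genes far higher. Fat, muscle and keratinocyte differentiation genes were lower with camera at the preset correlation but not with an estimated one (adjusted p = 0.0553, 0.285 and 0.436 with an estimated correlation). Ccl2 rose from -3.21 ± 0.11 (SD, n = 4) in syn to 0.68 ± 0.35 (SD, n = 5) in allo mice, a 14.9-fold difference (log2 3.89, SE 0.30, adjusted p = 7.96e-09). Saa3, an acute-phase serum amyloid, rose most, by log2 7.57 (SE 0.53, adjusted p = 2.32e-09). In both cases every allo mouse lay above every syn mouse. Of 14822 genes, 4172 passed the test, with 1864 higher and 2308 lower, and 1538 of them differed at least 2-fold.

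All 27 measured members of the interferon-gamma response list rose (mean log2 3.07), among them the chemokine Cxcl10 (5.79), the interferon-inducible GTPase Igtp (4.55) and the transcription factor Irf1 (3.50). On the type I interferon list 22 of 23 rose (mean 2.07), such as Isg15 (3.36), Rtp4 (2.79) and Bst2 (2.71). T cell genes rose in 13 of 15 cases (mean 2.47), with Cd8b1 at 6.28, Cd3d at 4.54 and Cd6 at 3.78, whereas Cd4 (0.23) and Il7r (-0.16) did not pass. All 12 cytotoxic and activated T and NK cell genes rose (mean 3.20), including Ccl5 (6.24), granzyme gene Gzmb (4.23) and Ifng (3.97). Macrophage and monocyte genes rose in 18 of 21 cases (mean 2.01), for example the receptor gene Clec7a (4.84), Fcgr4 (3.97) and Aif1 (2.51). Dendritic cell genes rose in 6 of 9 (mean 1.16), with Itgax at 2.13, Batf3 at 1.87 and Cd86 at 1.58. Among CC chemokines 9 of 17 rose (mean 1.77), with Ccl4 at 4.88, and Ccl12, a close mouse relative of Ccl2, rose by 3.33 (SE 0.49, adjusted p = 4.06e-05). Of 13 CXC chemokines 7 rose and 1 fell (mean 1.85), with Cxcl11 at 5.62 and Cxcl16 at 1.45. These 8 lists passed camera at the preset correlation and with an estimated one (adjusted p = 0.00265 to 0.0311 with an estimated correlation). Adjusted over the list alone, the counts were the same except for CC chemokines (9 higher, 1 lower), CXC chemokines (9 and 1), macrophages (18 and 1) and dendritic cells (6 and 1).

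Another 12 lists rose with camera at the preset correlation but not with an estimated one. Fry, run beside camera, called 26 of the 33 lists in this comparison. Antigen presentation by MHC class II had 5 of 9 members higher (mean 1.46, adjusted p = 0.183 with an estimated correlation), with the protease Ctss at 4.37, the class II activator Ciita at 2.81 and H2-DMa at 1.87. The Th1 and Th17 cytokine list had 6 of 10 higher (1.76, adjusted p = 0.0553 with an estimated correlation), including Il12rb1 (3.51) and Tnf (1.27). Proliferation genes were higher in 16 of 24 (0.92, adjusted p = 0.257 with an estimated correlation), with Birc5 at 1.52, Mcm3 at 1.08 and Bub1 at 1.03, and in 20 adjusted over the list alone. Complement genes were higher in 7 of 12 (0.81, adjusted p = 0.187 with an estimated correlation), with C1s1 at 2.33, Cfp at 1.97 and C1ra at 1.59. Chemokine receptors had 4 of 9 higher and 1 lower (1.22, adjusted p = 0.183 with an estimated correlation), with Cxcr6 at 4.35, Cxcr3 at 3.08 and Cxcr4 at 1.52. Neutrophil genes had 3 of 7 higher (1.48, adjusted p = 0.255 with an estimated correlation), namely Clec4d (5.37), Clec4e (3.46) and Lcn2 (3.21); the first 2 also mark monocytes. Genes of stressed keratinocytes had 6 of 16 higher and 2 lower (1.16, adjusted p = 0.292 with an estimated correlation), with Sprr2h at 3.32, Slpi at 2.92 and Krt16 at 1.88. Endothelial activation genes had 3 of 11 higher and 1 lower (0.58, adjusted p = 0.187 with an estimated correlation), with Vcam1 at 2.84, Icam1 at 2.40 and Tnfaip3 at 1.37. Immediate-early genes had 5 of 14 higher (0.44, adjusted p = 0.0598 with an estimated correlation), with Fos at 1.68, Junb at 1.45 and Atf3 at 1.14. The calls of 2 of these lists ended without a single mouse, that for endothelial activation without 6153 and that for stressed keratinocytes without 5702 or 6154. With only genes measured in every mouse, these 2 and chemokine receptors (mean 0.597) did not pass.

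Of genes that respond to IL-4 or IL-13, 6 of 17 rose (mean 0.88, adjusted p = 0.0553 with an estimated correlation). They were Ch25h (3.65), Socs1 (3.31), Chil3 (2.90), Ccl17 (2.53), Slc7a2 (2.35) and Il4i1 (1.38); Socs1 and Ch25h are also induced by interferons. The alternative activation genes Arg1 (-0.98), Retnla (-0.66) and Mrc1 (0.80) did not pass, and the call of the list ended when dim repeated values were treated as not measured (mean 0.387). On the Th2 cytokine and receptor list 2 of 13 rose (0.39, adjusted p = 0.255 with an estimated correlation), Crlf2 by 1.64 and Il4ra by 1.32 (SE 0.38, adjusted p = 0.0141). Il13 differed by 0.13 (SE 0.32, adjusted p = 0.806) and Il4 by 0.39 (SE 0.16, adjusted p = 0.0694), neither past the threshold. Both genes lay near a ratio of 0 in these mice, and whether their probes detected the transcripts was not tested. The Il4ra call ended without mouse 5700 (adjusted p = 0.0505), and that of the Th2 list without 5702.

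Scar-forming matrix did not rise as a group. Among 23 fibrillar matrix genes 1 rose and 2 fell (mean -0.30, camera adjusted p = 0.113), with Bgn at 1.36, Fmod at -1.58 and Col5a1 at -0.88, a call that ended without mouse 6153. Col1a1 differed by -0.20 (SE 0.30, adjusted p = 0.672), and its probes ranged from -0.84 to 0.18. The fibrosis activation list had 8 of 21 higher and 1 lower (0.58, adjusted p = 0.0812 with an estimated correlation). Its risers included the macrophage elastase Mmp12 (4.02), the protease inhibitor Timp1 (2.92), Tnc (2.11) and Tgfb1 (1.60, SE 0.26, adjusted p = 0.000136). Its call ended without mouse 5700, 5701, 5702, 5703 or 6152. Of 17 TGF-beta targets 4 rose and 1 fell (mean 0.00, camera adjusted p = 0.553), with Junb at 1.45, Bhlhe40 at 0.94 and Pmepa1 at 0.69; the last of these calls ended without 5700, 5701, 5703, 5704, 6151 or 6153.

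Adipocyte genes fell in 13 of 17 cases (mean -0.91, adjusted p = 0.0553 with an estimated correlation), with Slc2a4 at -1.51, Cidec at -1.12 and Retn at -1.08. Skeletal muscle genes fell in 12 of 22 (-0.77, adjusted p = 0.285 with an estimated correlation), with Eno3 at -1.41, Pvalb at -1.31 and Myoz1 at -0.86. Keratinocyte differentiation genes fell in 11 of 20 (-0.49, adjusted p = 0.436 with an estimated correlation), with Flg2 at -1.25, Krtdap at -0.80 and Lce1b at -0.76. That list lost its call after quantile normalization (mean -0.084), as did Flg2, Krtdap, Lce1b and Myoz1. Flg2 also lost its call without 5704 or 6153, and Krtdap without 6153. Basal keratinocyte genes fell in 4 of 12 (-0.40, adjusted p = 0.333 with an estimated correlation), with Trp63 at -1.33, Dst at -0.84 and Perp at -0.82. After quantile normalization the list, Trp63 and Perp did not pass, and the list call also ended without 5700, 5701, 5702, 5703, 6151, 6152 or 6153. Melanocyte and nerve genes fell in 4 of 9 (-0.69, adjusted p = 0.218 with an estimated correlation), with Pmel at -1.90, a call of the list that ended without 6151, 6153 or 6154. Adjusted over the list alone, 13 adipocyte, 15 muscle, 12 differentiation and 4 basal genes were lower.

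The remaining 6 lists passed in neither direction. Hair follicle genes had 3 of 17 higher and 1 lower (mean 0.98), endothelial genes 1 of 16 higher and 3 lower (-0.36), and sebaceous and lipid genes 1 of 12 higher and 2 lower (-0.53), with Fasn at -2.02 and Plin2 at 1.20. Mast cell genes had 2 of 10 higher and 1 lower (0.34), B and plasma cell genes 1 of 9 in each direction (-0.16), and smooth muscle and pericyte genes 1 of 11 in each direction (-0.29). Among genes measured in every mouse of both groups and with no overlap between them, the largest falls were those of Gng13 (-4.03), the retinol carrier Rbp4 (-3.72), Mt4 (-3.04), Btc (-2.91), Amy1 (-2.90), Il20ra (-2.85), Gsta3 (-2.77) and Aldh1a7 (-2.70). Saa1 (5.54), Acod1 (5.28) and Calhm6 (5.07) were among the largest rises. With the number series as a block 4174 genes passed. Within series 57 (2 allo, 3 syn) 2442 passed, 1258 of them higher. All 4172 genes kept their sign in series 57, and 99.6% of those with a value in series 61 (3 allo, 1 syn), but the same mice had defined these genes.

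**Figure D3:**
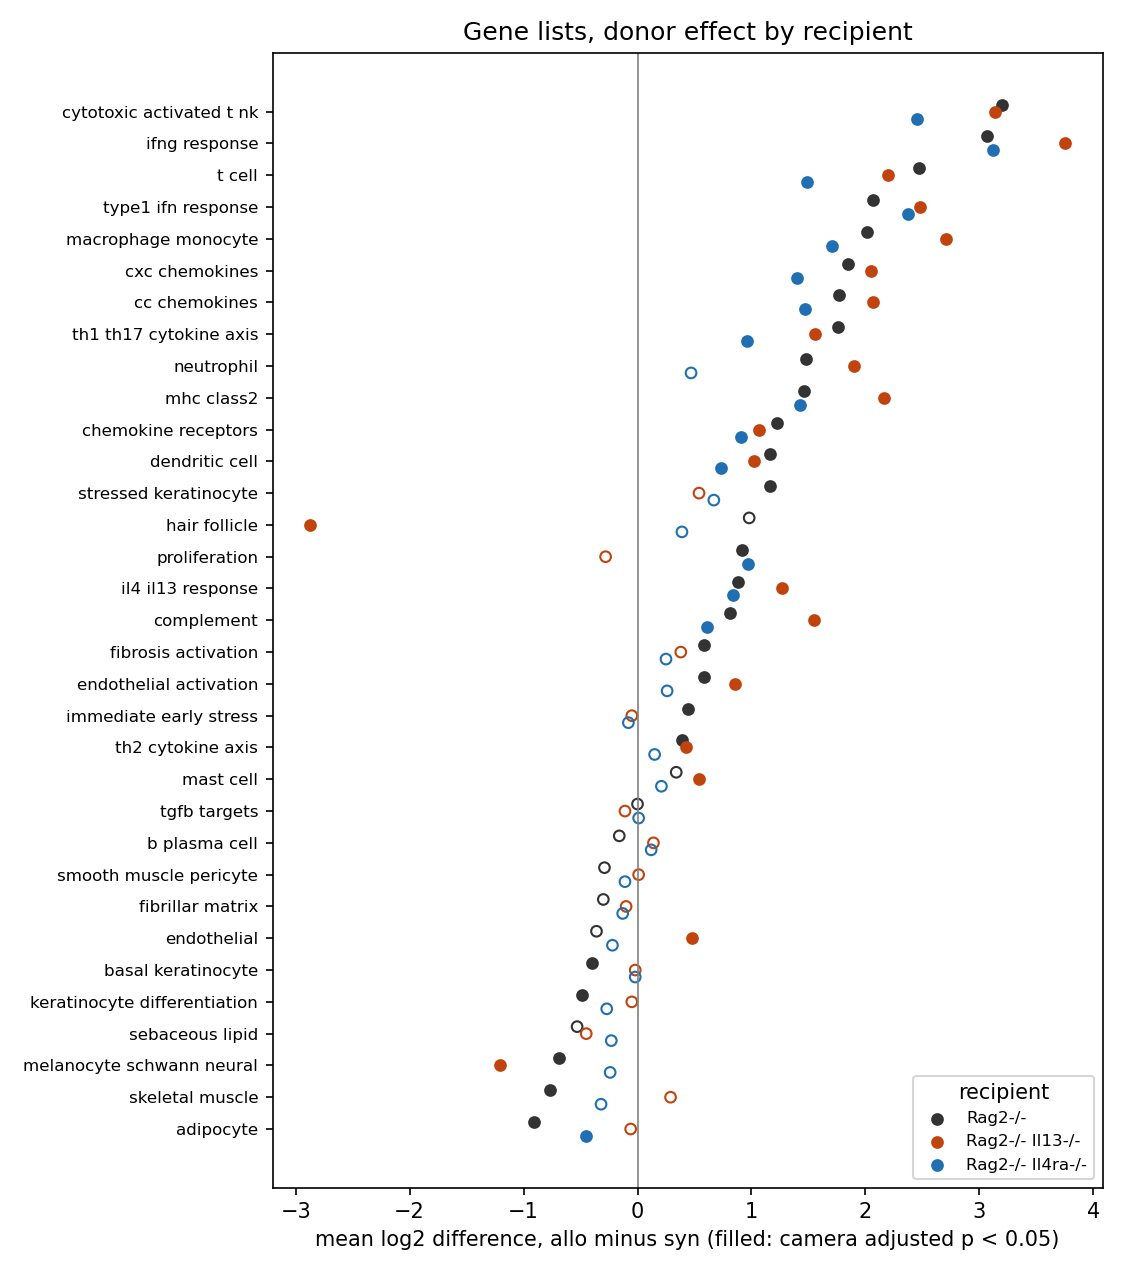
Mean log2 difference of allo minus syn mice for 33 gene lists in each kind of recipient. Filled points passed camera at the preset correlation with an adjusted p under 0.05; the interferon-gamma response list lies at 3.07, 3.75 and 3.12.

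In Il13-deficient recipients allogeneic cells again raised interferon, T cell, macrophage, chemokine and complement genes. Hair follicle genes were lower in allo than in syn mice, among which 6229 and 6234 had high scores. Ccl2 rose from -3.82 ± 0.45 (SD, n = 4) to -0.40 ± 0.91 (SD, n = 4), a 10.7-fold difference (log2 3.42, SE 0.32, adjusted p = 8.35e-08), with no overlap between allo and syn mice. In all, 2412 genes passed, 1359 higher and 1053 lower. Interferon-gamma response genes rose in 26 of 27 (mean 3.75), with Cxcl10 at 6.13 and Igtp at 5.23, and type I interferon genes in 23 of 23 (2.48). Macrophage genes rose in 19 of 21 (2.71), with Clec7a at 5.23 and Fcgr4 at 4.21. T cell genes rose in 12 of 15 (2.20), with Cd8b1 at 6.38 and Cd3d at 4.87, while Cd4 fell by 1.64. Cytotoxic genes rose in 11 of 12 (3.14), with Ccl5 at 6.14 and Gzmb at 4.27. Complement rose in 9 of 12 (1.55) and MHC class II in 6 of 9 (2.16). CC chemokines rose in 12 of 17 (2.07), with Ccl4 at 5.19 and Ccl12 at 3.55, and CXC chemokines in 8 of 13 (2.05), with Cxcl11 at 5.33. Genes that respond to IL-4 or IL-13 rose in 9 of 17 (1.27, adjusted p = 0.000842 with an estimated correlation), among them Chil3 (3.54), Ch25h (2.84), Socs1 (2.66), Ccl17 (2.07), Mrc1 (1.98) and Ccl11 (1.54). All of these lists kept their call with an estimated correlation, as did Th1 and Th17 cytokines (1.56), dendritic cells (1.02), endothelial activation (0.86) and hair follicle (adjusted p = 0.000566 to 0.027 with an estimated correlation). Adjusted over the list alone, 9 MHC class II, 10 IL-4 or IL-13 response and 12 T cell genes were higher.

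Hair follicle genes fell in 11 of 17 cases in Il13-deficient recipients (mean -2.87, adjusted p = 0.027 with an estimated correlation; 14 adjusted over the list alone), with Krt34 at -5.65 and Padi3 at -5.10. The largest falls with no overlap between groups were of the same kind: the hair shaft gene Prr9 (-5.30), the hair keratin partners Krtap6-1 (-4.84), Krtap5-1 (-4.39), Krtap5-4 (-4.26) and Krtap16-3 (-3.89), the hair cuticle gene S100a3 (-4.07), Mycn (-4.12) and Msx2 (-3.61), a member of the list. These falls moved with mice 6229 and 6234, whose hair follicle scores of 3.68 and 4.58 compared with 1.18 and 1.72 in the other syn mice of the group. Without these 2 mice 1431 genes passed, and of the genes just named S100a3 and Mycn alone kept their calls. Without 6229 alone Krtap16-3 lost its call, and without 6234 alone Krtap16-3 and Krtap6-1 did.

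Further lists passed camera in these recipients at the preset correlation but not with an estimated one, while fry called 19 of the 33 lists. Endothelial genes (0.48, adjusted p = 0.331 with an estimated correlation) lost their call without 6229, and the mean was 0.013 without both mice. Chemokine receptors (1.07, adjusted p = 0.214 with an estimated correlation) lost it without 6234. Th2 cytokines and receptors (0.43, adjusted p = 0.25 with an estimated correlation) lost it without 6224 or 6234, and mast cell genes (0.54, adjusted p = 0.276 with an estimated correlation) without 6224, 6226, 6229, 6232 or 6234. Neutrophil genes rose in 4 of 7 (1.90, adjusted p = 0.0746 with an estimated correlation), and melanocyte and nerve genes fell in 3 of 9 (-1.21, adjusted p = 0.115 with an estimated correlation). Il4ra rose by 1.64 (SE 0.40, adjusted p = 0.0069) and Tgfb1 by 1.12 (SE 0.28, adjusted p = 0.00733); neither passed without 6229 and 6234 (adjusted p = 0.127 and 0.0648). Saa3 rose by 6.22 and Gbp8 by 5.44. Col1a1 fell by 1.02 (SE 0.32, adjusted p = 0.0314), a call that ended without 6223, 6224, 6225, 6229 or 6234. Il13 differed by -0.95 (SE 0.36, adjusted p = 0.0813). Keratinocyte differentiation (-0.05), adipocyte (-0.06), muscle (0.29), fibrillar matrix (-0.10), fibrosis activation (0.38), TGF-beta target (-0.11), stressed keratinocyte (0.54) and proliferation (-0.28) lists did not pass. The last turned to 0.39 and passed without 6229 and 6234. All mice of this comparison share series 62, and with series as a block in the whole fit 2314 genes passed; with only these groups fitted 790 did, 662 higher and 128 lower. With array weights 3943 passed, 1935 higher and 2008 lower.

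In Il4ra-deficient recipients the interferon, T cell, cytotoxic and macrophage genes rose too. Ccl2 rose from -3.55 ± 0.16 (SD, n = 3) to -0.72 ± 0.31 (SD, n = 4), a 7.11-fold difference (log2 2.83, SE 0.34, adjusted p = 1.01e-05), again with no overlap of the groups. Of 14822 genes 1362 passed, 874 higher and 488 lower. After median centring the higher share was 73.8% against 64.2% here. Interferon-gamma response genes rose in 26 of 27 (mean 3.12), with Cxcl10 at 5.75 and Igtp at 4.72, and type I interferon genes in 22 of 23 (2.37), with Isg15 at 3.88. Cytotoxic genes rose in 11 of 12 (2.45), with Ccl5 at 4.46 and Gzmb at 4.02. T cell genes rose in 10 of 15 (1.49; 11 adjusted over the list alone), with Cd8b1 at 4.58, Cd3d at 3.87 and Cd6 at 2.52. Macrophage genes rose in 15 of 21 (1.71; 17 adjusted over the list alone), with Clec7a at 3.82 and Fcgr4 at 3.47. CC chemokines rose in 8 of 17 (1.47), with Ccl4 at 4.38 and Ccl12 at 2.82, and CXC chemokines in 6 of 13 (1.40), with Cxcl11 at 5.51. Dendritic cell genes had 2 of 9 higher and 1 lower (0.73). Genes that respond to IL-4 or IL-13 rose in 5 of 17 (0.84), namely Socs1 (3.58), Ch25h (3.15), Ccl17 (2.53), Il4i1 (1.07) and Cish (0.70), although the list lost its call when dim repeated values were treated as not measured (0.542). These 9 lists passed with an estimated correlation as well (adjusted p = 0.000322 to 0.0144 with an estimated correlation).

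Fry called 15 of the 33 lists in Il4ra-deficient recipients. Beyond the lists above, some passed camera at the preset correlation but not with an estimated one. They were MHC class II (5 of 9 higher, mean 1.43, adjusted p = 0.119 with an estimated correlation), Th1 and Th17 cytokines (4 of 10, 0.96, adjusted p = 0.155 with an estimated correlation) and chemokine receptors (2 of 9, 0.91, adjusted p = 0.162 with an estimated correlation). Proliferation genes were higher in 7 of 24 (0.97, adjusted p = 0.259 with an estimated correlation; 19 adjusted over the list alone) and complement genes in 5 of 12 (0.61, adjusted p = 0.259 with an estimated correlation). The adipocyte list passed with 0 of 17 single members past the threshold (-0.45, adjusted p = 0.348 with an estimated correlation), and lost its call without 4534 or 4535. Its mean was -0.96 in series 45 (2 allo, 1 syn) and -0.10 in series 57 (2 allo, 2 syn). Among other large changes were F7 (3.87), Clec4n (3.96), Saa3 (4.61), Gng13 (-3.10), Rbp4 (-2.12) and Btc (-2.04). Tgfb1 rose by 1.13 (SE 0.30, adjusted p = 0.0221), a call that ended without 4533, 5717 or 5720. Il4ra differed by 0.77 (SE 0.43, adjusted p = 0.287), Il13 by -0.08 (SE 0.41, adjusted p = 0.93), Il4 by 0.33 (SE 0.18, adjusted p = 0.262) and Col1a1 by -0.22 (SE 0.35, adjusted p = 0.749), with probes of Col1a1 from -0.49 to 0.26. The count fell to 839 without mouse 4533, 848 without 4535, 596 without 5717 and 790 without 5718. With exact 0 kept as a value it was 880. Lists that did not pass included neutrophil (0.47), Th2 (0.15), fibrosis activation (0.25), fibrillar matrix (-0.13), TGF-beta target (0.01), keratinocyte differentiation (-0.27) and muscle genes (-0.32). With series as a block 1185 genes passed; within series 57 (2 allo, 2 syn) 376 passed, 341 of them higher, and all called genes with a value kept their sign there and in series 45 (2 allo, 1 syn), mice that had also defined them.

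The donor effects, measured in separate mice, overlapped between recipients. In Rag2-/- and Il13-deficient recipients 1024 genes were higher in both (171 expected for independent lists) and 452 lower in both (164 expected), with 13 in opposite directions. In Rag2-/- and Il4ra-deficient recipients 784 were higher in both (110 expected) and 399 lower (76 expected), with 0 opposite. In the deficient recipients 654 were higher in both (80 expected) and 151 lower (35 expected), with 1 opposite. The fit used 1 estimate of spread per gene for all comparisons, so unrelated effects could also overlap more than these expected counts. Across all genes, which are not independent replicates, r of the donor effects was 0.635, 0.798 and 0.605 in the same order. Of the 4172 genes called in Rag2-/- recipients, 85.6% had the same sign in Il13-deficient and 96.5% in Il4ra-deficient mice. The median effect of the 1864 higher genes was 0.97 in the Rag2-/- mice that defined them, 0.69 in Il13-deficient and 0.64 in Il4ra-deficient mice. For the 2308 lower genes it was -0.75, -0.28 and -0.46 in the same order. The genes were picked in Rag2-/- mice, and how much picking alone lowers the other values was not estimated.

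Whether lack of Il13 or Il4ra in the recipient altered the donor effect was tested directly. For Il13, 2 genes passed, Tspan12 (difference of effects 1.78, SE 0.30) and Gpat3 (1.72, SE 0.27), both with adjusted p = 0.042, and 2376 had an unadjusted p under 0.05. Both calls were lost, with 0 genes left, under quantile normalization, no filter, single probes, only the groups compared, number series as a block and without 6229 and 6234, whereas array weights gave 3195 genes. Tspan12, a cell-surface tetraspanin, went from 3.39 ± 0.22 (SD, n = 4) in syn to 1.52 ± 0.24 (SD, n = 5) in allo Rag2-/- mice, and from 2.73 ± 0.51 (SD, n = 4) to 2.64 ± 0.30 (SD, n = 4) in Il13-deficient mice. Gpat3, an enzyme of triglyceride synthesis, went from 2.32 ± 0.43 (SD, n = 4) to 0.90 ± 0.34 (SD, n = 5), and from 1.41 ± 0.12 (SD, n = 4) to 1.72 ± 0.24 (SD, n = 4). For Il4ra 0 genes passed in limma (730 at an unadjusted p under 0.05; 21 with array weights), and between the deficient recipients 0 passed (1839; 1701 with array weights). Ccl2 did not differ past the threshold. Its donor effect differed by -0.48 (SE 0.44, 95% interval -1.39 to 0.43, adjusted p = 0.619) with Il13 deficiency, and by -1.06 (SE 0.45, 95% interval -2.01 to -0.12, adjusted p = 0.995, unadjusted p = 0.0292) with Il4ra deficiency. The Il13 count was 0 without 5700, 5701, 5703, 6152, 6223, 6226, 6229, 6232 or 6234, 1 without 5702, 6153 or 6154, 4 without 5704, 52 without 6230, 87 without 6224 and 849 without 6225. Between the deficient recipients it was 1 without 5720 or 6234, 8 without 6226 and 463 without 6225.

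Gene lists differed between donor effects more often than single genes. With Il13 deficiency 13 lists passed at the preset correlation, and 2 also with an estimated correlation: hair follicle (mean difference -3.85, adjusted p = 0.0109 with an estimated correlation) and immediate-early genes (-0.48, adjusted p = 0.0109 with an estimated correlation). The hair follicle difference accompanies the high scores of syn mice 6229 and 6234. With Il4ra deficiency 12 lists passed, and 2 also with an estimated correlation. T cell genes rose less (-0.97, adjusted p = 0.0191 with an estimated correlation; fry adjusted p = 0.0971), with 0 of 15 past the threshold over all genes and 6 lower adjusted over the list alone, and immediate-early genes differed by -0.52 (adjusted p = 0.00098 with an estimated correlation). Between the deficient recipients 15 passed, and hair follicle alone with an estimated correlation (3.26, adjusted p = 0.0451 with an estimated correlation).

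**Figure D4:**
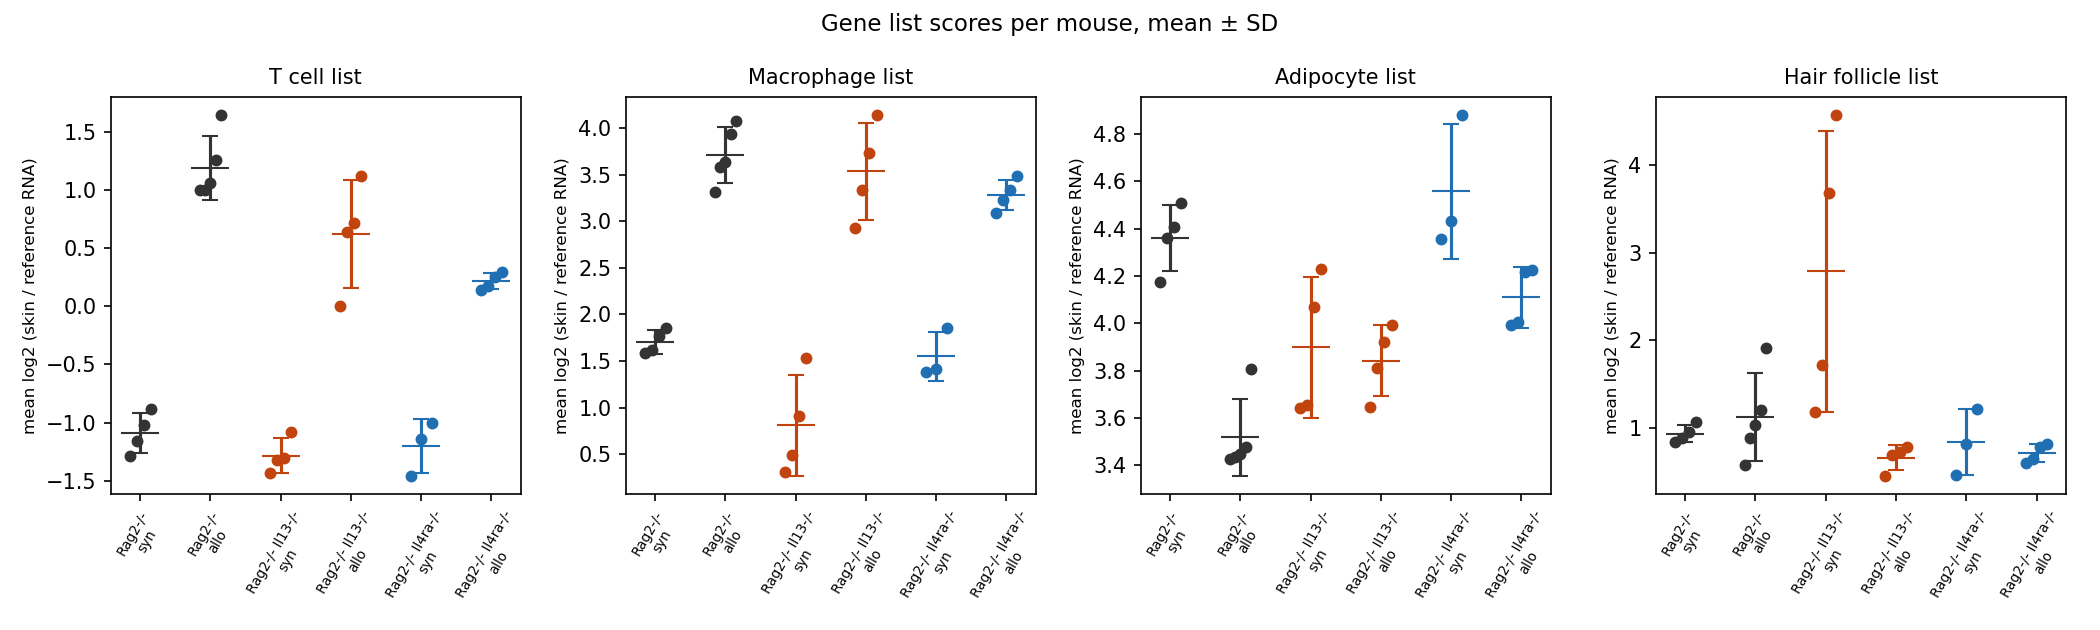
Scores of the T cell, macrophage, adipocyte and hair follicle lists per mouse, as the mean log2 of skin over reference RNA over list members measured in all mice; bars show mean ± SD. Allo Il4ra-deficient mice lie at 0.14 to 0.29 on the T cell list and allo Rag2-/- mice at 1.00 to 1.65.

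Under the same allogeneic donor, skin of Il4ra-deficient recipients held lower levels of T cell and cytotoxic genes than skin of Rag2-/- recipients. T cell genes were lower by a mean of -1.04 (4 of 15 lower, 12 adjusted over the list alone; adjusted p = 0.0042 with an estimated correlation), and the score was 0.22 ± 0.07 (SD, n = 4) against 1.19 ± 0.28 (SD, n = 5). Cytotoxic genes were lower by a mean of -0.91 (2 of 12, 7 adjusted over the list alone; adjusted p = 0.0393 with an estimated correlation). Not all of them fell: Gzmb lay at 4.46 ± 0.19 (SD, n = 4) in Il4ra-deficient and 4.36 ± 0.31 (SD, n = 5) in Rag2-/- mice. Ifng lay at 3.71 ± 0.53 (SD, n = 4) and 4.09 ± 0.30 (SD, n = 5). Ccl2 fell by 1.40 (SE 0.30, adjusted p = 0.0306), from 0.68 ± 0.35 (SD, n = 5) to -0.72 ± 0.31 (SD, n = 4). The scavenger receptor gene Marco fell most, by 3.03 (SE 0.45, adjusted p = 0.00907), from 4.75 ± 0.62 (SD, n = 5) to 1.73 ± 1.31 (SD, n = 4). With syngeneic cells Marco was also lower, at 0.26 ± 0.50 (SD, n = 3) against 2.21 ± 0.32 (SD, n = 4), a difference of -1.95 (SE 0.51, adjusted p = 1) that did not pass. In all 119 genes passed, 40 higher and 79 lower. Dnah2 (-2.97), Saa3 (-2.65), Saa1 (-2.27) and Sh2d1a (-2.26), a signalling adaptor of T and NK cells, were lower, as were Ccl5 (-1.62), Cd6 (-1.33) and Clec4d (-2.21). Cyp2g1 (3.49), the glycogen synthase gene Gys2 (2.55), Rbp4 (2.29), Ccr6 (2.14) and Aldh1a7 (2.02) were higher. The dendritic cell (-0.55), fibrosis activation (-0.29) and immediate-early (-0.39) lists were lower and the adipocyte list higher (0.62), with adjusted p = 0.0141 to 0.0283 with an estimated correlation; fibrosis activation did not pass with only genes measured in every mouse. Il4ra itself was lower by -1.47 (SE 0.38, adjusted p = 0.0734), past no threshold.

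Of the 18 lists called in that comparison, 12 lost their call with an estimated correlation, including neutrophil (-1.23, adjusted p = 0.0539 with an estimated correlation), CC chemokine (-0.51, adjusted p = 0.138 with an estimated correlation), CXC chemokine (-0.66, adjusted p = 0.138 with an estimated correlation) and macrophage genes (-0.43, adjusted p = 0.419 with an estimated correlation). With the number series as a block 3 genes passed, and the Ccl2 difference was -1.51 with an adjusted p of 0.174. Marco kept its call under each of the 23 alternatives in which it was tested (adjusted p 0.000389 to 0.0437), whereas Ccl2 was tested in 24. The count was 56 without mouse 4533, 24 without 4534, 19 without 5701, 24 without 5704, 12 without 5718, 6 without 5720, 27 without 6151 and 46 without 6154, and Ccl2 lost its call without any of these 8.

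The other recipient comparisons gave few calls. Between allo Il13-deficient and allo Rag2-/- mice limma called 0 genes (853 at an unadjusted p under 0.05; 239 with array weights), with 2 without mouse 6151 and 81 without 6224. Ccl2 differed there by -1.08 (SE 0.30, adjusted p = 0.41), at -0.40 ± 0.91 (SD, n = 4) against 0.68 ± 0.35 (SD, n = 5). Allo Il4ra-deficient mice, whose Ccl2 difference passed, lay at -0.72 ± 0.31 (SD, n = 4). Allo mice of the deficient recipients were not compared with each other, so these calls do not show that Ccl2 differs between them. Lists for immediate-early genes (-0.44, adjusted p = 1.47e-05 with an estimated correlation), fibrosis activation (-0.36, adjusted p = 0.0311 with an estimated correlation) and dendritic cells (-0.38, adjusted p = 0.0427 with an estimated correlation) were lower, the last call ending without 6226. T cell genes differed by -0.52 (adjusted p = 0.0667 with an estimated correlation). Between syn Il4ra-deficient and syn Rag2-/- mice limma called 0 genes (430 at an unadjusted p under 0.05; 3 with array weights), 1 without mouse 5719, and none of the 7 lists called at the preset correlation kept its call (adjusted p = 0.558 to 0.836 with an estimated correlation).

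Between syn Il13-deficient and syn Rag2-/- mice 42 genes passed, 19 higher and 23 lower. The count was 3879 with array weights, 329 with all arrays and a random mouse block, 5 after quantile normalization and 0 with the share of exact 0 as a covariate. The higher ones included the hair keratin partner Krtap5-1 (4.45), the gluconeogenic enzyme gene Fbp1 (3.97), the hair keratin Krt87 (3.82), Mycn (3.67) and Slc45a2 (2.66), a melanocyte transporter. Pyy (-2.60), Marco (-2.46), the interferon-induced Xaf1 (-2.45), Pdk4 (-1.89) and Ptpro (-1.84) were lower. Of 17 lists called by camera, hair follicle alone kept its call with an estimated correlation (2.82, adjusted p = 0.0212 with an estimated correlation), while fry called 16 of the 33 lists. Interferon-gamma response (-0.92), macrophage (-0.87) and skeletal muscle genes (-0.89) were lower and proliferation genes higher (0.92), with adjusted p = 0.119 to 0.142 with an estimated correlation. Hair follicle scores were 2.79 ± 1.61 (SD, n = 4) in syn Il13-deficient and 0.93 ± 0.10 (SD, n = 4) in syn Rag2-/- mice. Without 6229 and 6234, 3 genes passed. The count was 0 without 5700, 5703 or 6234, 1 without 6229, 11 without 5702, 27 without 6153, 979 without 6230 and 1821 without 6225. Exact 0 kept as a value changed the split to 34 higher and 15 lower.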

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

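The tests on hair follicle genes, on dilution, scaling and number series of the tissue lists, and on T cell against macrophage genes were chosen only after the results were seen; the permuted groups and the other T cell tests were chosen before.

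Permuted groups were used to ask whether chance could be the source of a count. The donor comparison gave 4172 genes in Rag2-/- recipients, the most of 100 splits of the same mice (highest other 2936; 1 split as large, the real one). In Il13-deficient recipients it gave 2412 (highest other 946; 1 of 35) and in Il4ra-deficient recipients 1362 (highest other 70; 1 of 35). The 119 genes between allo Il4ra-deficient and allo Rag2-/- mice were also the most (highest other 2; 1 of 100). The median of the other splits was 0 in all 4 comparisons. The split with 2936 genes put 6152 with the syn mice 5700, 5702, 5703 and 6153, and so still largely parted the donors. Chance likely does not account for these 4 counts, but these splits ignore number series, and with series as a block 3 genes passed in the last comparison. The 2 genes of the Il13 difference of donor effects were reached by 3 of 100 splits, the real one included. The highest other split gave 115, which points to a structure of the samples. With series as a block 0 genes passed, and leaving out single mice such as 6229 or 5700 also gave 0. The splits therefore do not settle whether chance gave these 2 calls.

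Chance could account for the 42 genes between syn Il13-deficient and syn Rag2-/- mice, which 4 of 35 splits reached, and the highest, 1035, put 6153 with 6229, 6230 and 6234. For counts of 0 the splits say nothing on chance, because any split has at least 0 genes: 100 of 100 for the Il4ra difference (highest 2), 100 of 100 between the deficient recipients (highest 955), 35 of 35 for syn Il4ra-deficient mice (highest 2) and 100 of 100 for allo Il13-deficient mice (highest 546). Splits of 955, 1035 and 546 genes suggest that variation among mice, such as that of 6229, 6234 and 6224, may exceed the effect of recipient genotype.

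Hair follicle genes were high in 2 syn Il13-deficient mice, with scores of 3.68 (6229) and 4.58 (6234). Lack of Il13 or number series 62 might raise them, but that 4 of 4 mice of the group lay above the highest syn Rag2-/- mouse gives little support, as the lowest had 1.18 against 1.06 on a score of 4 genes, and the allo Il13-deficient mice, of the same genotype and series, averaged 0.66 against 0.93 in syn Rag2-/- mice. Neither can be told from the other. Syn mice 6225 and 6230 share this genotype and series yet scored 1.18 and 1.72. Neither alone therefore accounts for the split within the group, and what set 6229 and 6234 apart stays open. The share of unmeasured probes differed by 29.9 percentage points between the 2 mice, at 2.42% in 6229 and 32.4% in 6234, around a median of 24.6%. A shift of that share in 1 direction is thus an unlikely source, but effects at both extremes are not excluded. With the share as a covariate, 0 genes passed between syn Il13-deficient and syn Rag2-/- mice, against 42 without it. On the muscle list 0 of the 2 exceeded the other mice of the group; their scores of 4.42 and 4.44 lay below 5.29 and 5.56, so pieces of skin with less muscle are not excluded.

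Adipocyte, muscle and keratinocyte differentiation genes were lower in allo than in syn Rag2-/- mice. Dilution by RNA of incoming cells would lower adipocyte and endothelial scores alike. The adipocyte score fell by 0.84 while a score of 7 endothelial genes changed by 0.04 (exact permutation p = 0.0238), which goes against dilution alone. However, all 16 endothelial genes had a mean of -0.36, with 3 lower and 1 higher, so dilution is left open. Taken over all 3 lists, as first tested, 5 of 6 calls were kept under 2 scalings. Array scaling likely does not explain the adipocyte and muscle falls (4 of 4 calls kept), but it could explain the keratinocyte fall (1 of 2 kept). Within number series 6 of 6 list means lay below 0, but series 61 has 1 syn mouse and the same mice defined the falls, so series could still play a part.

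T cell genes were lower in allo Il4ra-deficient than in allo Rag2-/- mice. The score also differed within series 57, by -1.29, but over 2 mice on each side that helped define the difference. With series as a block 3 genes passed in this comparison, against 119 without it, so number series is left open. The share of unmeasured probes likely does not explain the lower T cell genes (-1.032 with that share as a covariate). A reaction weaker as a whole might lower all cell lists alike, whereas the T cell score differed by -0.98 and the macrophage score by -0.42 (exact permutation p = 0.0317). That difference may in part also reflect the different range of the lists, as the donor effect on them was 2.47 and 2.01 in Rag2-/- mice. Genotype of the recipient remains a candidate explanation.

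Single mice stood apart from their group in 15 of 202 sets of values checked, and chance alone would mark about 1 in 20. Among allo Rag2-/- mice, 5704 had cytotoxic genes at 3.86 (others 2.87 to 3.06), proliferation genes at -1.4 (others -1.92 to -1.8) and Il4ra at 3.27 (others 1.69 to 1.96). Mouse 6152 had IL-4 and IL-13 response genes at 2.63 (others 2.93 to 3.02) and smooth muscle genes at 1.01 (others 0.7 to 0.789), and 6154 had adipocyte genes at 3.81 (others 3.42 to 3.48). Among syn Il13-deficient mice, 6229 had sebaceous genes at 2.76 (others 3.03 to 3.08), 6234 melanocyte and nerve genes at 1.97 (others 2.53 to 2.62), and 6230 Col1a1 at -0.469 (others 0.173 to 0.244). Allo Il13-deficient mouse 6224 had neutrophil genes at 1.93 (others -0.318 to 0.02), stressed keratinocyte genes at 3.46 (others 2.36 to 2.47), sebaceous genes at 1.4 (others 2.77 to 2.87) and endothelial activation genes at 1.28 (others 0.566 to 0.686). Among allo Il4ra-deficient mice, 5720 had smooth muscle genes at 0.673 (others 0.784 to 0.804) and 5718 Il13 at -0.621 (others 0.651 to 0.812).

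The donor effect differed between Il13-deficient and Rag2-/- recipients for Tspan12 (1.78) and Gpat3 (1.72). At the preset correlation the signed difference was above 0 for the lists of interferon-gamma (0.69), type I interferon (0.42), MHC class II (0.7), macrophage (0.71), keratinocyte differentiation (0.45), basal keratinocyte (0.39), adipocyte (0.85), muscle (1.06), endothelial (0.84) and complement genes (0.74). Of these, type I interferon turned to -0.042 without 6229 and 6234, and keratinocyte differentiation to -0.008 after quantile normalization and -0.193 with exact 0 kept. Syn mice 6229 and 6234 had lower adipocyte scores (3.65 and 3.64, others 4.23 and 4.07), muscle scores (4.42 and 4.44, others 5.29 and 5.56) and keratinocyte differentiation scores (4.59 and 4.99, others 5.46 and 5.68), so these differences may rest on the 2 mice. Both were also lower on the interferon-gamma (-0.45 and -0.64, others 0.51 and 0.53), macrophage (0.49 and 0.31, others 1.53 and 0.91) and complement lists (1.96 and 1.85, others 2.87 and 2.42). The same held for the MHC class II, endothelial and basal keratinocyte lists. Their proliferation scores were higher (-1.10 and -1.11, others -3.02 and -1.87). The differences on these lists may rest on the 2 mice as well. The difference was below 0 for hair follicle (-3.85), proliferation (-1.2) and immediate-early genes (-0.48). With an estimated correlation 2 of these 13 lists passed, hair follicle and immediate-early. Between Il4ra-deficient and Rag2-/- recipients, 12 lists differed at the preset correlation and 2 of them, T cell and immediate-early, also with an estimated one: Th1 and Th17 (-0.8), type I interferon (0.31), T cell (-0.97), cytotoxic (-0.75), macrophage (-0.3), neutrophil (-1.01), keratinocyte differentiation (0.22), basal keratinocyte (0.39), adipocyte (0.46), muscle (0.44), melanocyte and nerve (0.45) and immediate-early genes (-0.52).

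Between Il4ra-deficient and Il13-deficient recipients 15 lists differed at the preset correlation, of which 1, hair follicle, passed with an estimated correlation and 0 with fry: interferon-gamma (-0.63), MHC class II (-0.73), CC chemokine (-0.61), T cell (-0.71), cytotoxic (-0.69), macrophage (-1.01), neutrophil (-1.42), hair follicle (3.26), adipocyte (-0.39), muscle (-0.62), endothelial (-0.71), endothelial activation (-0.6), complement (-0.94), proliferation (1.25) and melanocyte and nerve genes (0.97). Genes with a probe measured in all allo and no syn mice numbered 8 in Rag2-/-, 3 in Il13-deficient and 34 in Il4ra-deficient recipients, and those with a probe measured in all syn and no allo mice 2, 40 and 3. Of the former, 2, 1 and 11 were tested through other probes, among them Mcemp1 (3.81 on the 1-sided probe), the T cell gene Cd8a (3.56) and Sox17 (3.66). Each of these was the highest 1-sided probe of its recipient. Many others lay near a ratio of 0, such as Ccr3 (-0.27) in Rag2-/-, Mcc (0.08) in Il13-deficient and Vmn1r189 (-0.01) in Il4ra-deficient mice. How many such genes missing values alone would give was not estimated.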

How the results depend on the processing

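Alternatives with exact 0 kept, dim repeated values removed, the share of exact 0 as a covariate, and mice 6229 and 6234 left out were chosen only after the results were seen. In this paragraph D stands for the donor comparison, I for the difference of donor effects, S for syn and A for allo recipients compared with Rag2-/- mice, and counts are genes unless lists are named. Main counts were 4172, 2412 and 1362 for D in Rag2-/-, Il13-deficient and Il4ra-deficient mice; 2, 0 and 0 for I (Il13, Il4ra, and between the deficient recipients); 42 and 0 for S, and 0 and 119 for A (Il13, Il4ra). The cause of each change below was not tested. Quantile normalization gave 0 for I of Il13 and 5 for S of Il13, and keratinocyte differentiation turned to -0.008 in I of Il13. Genes measured in every mouse gave 10 (I, Il13), 1 (I between the deficient) and 64 (S, Il13). No filter gave 0 (I, Il13), 18 (S, Il13), 72 (A, Il4ra) and 4 lists (S, Il4ra). Single probes gave 0 (I, Il13) and 8 (S, Il13). All arrays with a random mouse block gave 12 (I, Il13), 21 (I between the deficient), 329 (S, Il13), 1 (S, Il4ra) and 1 (A, Il13). With 1 array per mouse there were 4 (I, Il13), 24 (S, Il13) and 4 lists (S, Il4ra). Only the groups compared gave 790 (D, Il13), 0 (I, Il13), 4 (S, Il13) and 213 (A, Il4ra). Number series as a block gave 0 (I, Il13), 6 (I between the deficient) and 3 (A, Il4ra). Array weights, which ran from 0.26 (6224) to 3.99 (5703), gave 6345, 3943 and 3155 for D, 3195, 21 and 1701 for I, 3879 and 3 for S, and 239 and 928 for A. Exact 0 kept gave 880 (D, Il4ra), 4 (I, Il13), 2 (I between the deficient), 66 (A, Il4ra) and 4 lists (S, Il4ra); keratinocyte differentiation turned to -0.193 (I, Il13) and 0.109 (S, Il13), and endothelial genes to 0.249 (S, Il13). Dim values removed gave 18 (I, Il13), 1 (I between the deficient), 123 (S, Il13) and 1 (A, Il13). The share of exact 0 as a covariate gave 0 (S, Il13) and 78 (A, Il4ra). Without 6229 and 6234 there were 1431 (D, Il13), 0 (I, Il13), 1 with 9 lists (I between the deficient), 3 (S, Il13), 4 (A, Il13) and 214 (A, Il4ra). Without them signs turned for proliferation (D of Il13, 0.39), type I interferon (I of Il13, -0.042; I between the deficient, 0.348), basal keratinocyte (S of Il13, 0.02) and endothelial genes (S of Il13, 0.118). An estimated correlation left 8 and 9 lists for D (Rag2-/-, Il4ra), 2, 2 and 1 for I, 1 and 0 for S, and 3 and 6 for A. Fry gave 26, 19 and 15 lists for D, 7, 1 and 0 for I, 16 and 0 for S, and 2 and 6 for A. Leaving out each mouse gave 2922 to 4274, 1771 to 2869 and 596 to 1114 for D; 0 to 849, 0 to 0 and 0 to 463 for I; 0 to 1821 and 0 to 1 for S; 0 to 81 and 6 to 105 for A. Lists ran from 21 to 26, 17 to 22 and 14 to 17 for D; 10 to 14, 8 to 16 and 9 to 18 for I; 14 to 19 and 3 to 12 for S; 12 to 22 and 15 to 20 for A. Of 2792, 2619 and 2518 values of named genes in D, 99, 63 and 122 were weaker. Among values called in the main or the alternative run 0 turned sign, and signs of values called in neither were not compared. Many of these genes were named for large changes in D itself, so a turn was unlikely. The counts of recipient comparisons, such as 0 to 1821 for S of Il13, may depend on single mice.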
